A study of Mus musculus with 27 samples.

How the data were processed

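The series measured chromatin occupancy and RNA in mouse embryonic stem cells, pluripotent cells that self-renew in culture, around WDR43, a WD-repeat protein of the nucleolar complex that processes ribosomal RNA precursors. The labels describe 27 samples. Chromatin immunoprecipitation sequencing (ChIP-seq) with a FLAG antibody mapped tagged WDR43, and ChIP-seq for 3 forms of RNA polymerase II (Pol II) and RNA sequencing with spike-in RNA compared control short hairpin RNA (shCtl) with short hairpin RNA against WDR43 (shWDR43). For ChIP it is not stated whether the numbers 1 and 2 mark replicates or hairpins. Samples were grouped from their titles and characteristics. The 6 samples of the input, the full-length, N-terminal and C-terminal constructs and the chromatin-directed purification and crosslinking assays are not analysed here.

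The authors deposited 1 peak list for each of 17 ChIP libraries, with chromosome, start, end, a MACS peak name and a score per peak. The deposited score is the authors' own value for each peak and was at least 50 in every list. It was used here only to rank, filter and compare peaks within a list. Per the submitters' processing notes, ChIP reads were aligned with Bowtie2 to the mouse genome build mm9. The caller's version, its threshold and the control library are not given in the sources used here, and the depth of the ChIP libraries is unknown. Peaks were called per library, so each Pol II group holds 2 separate lists and each WDR43 condition holds 1.

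For RNA, the authors deposited a table of 38582 genes with 1 FPKM-like value per gene and library. TopHat and Cufflinks are named per the submitters' processing notes, and FPKM (fragments per kilobase of transcript, scaled to the sequenced fragments) was inferred from Cufflinks, since the table itself does not write the unit. Per the file headers there were 2 biological replicates per group, and the title of the table names spike-in. Per the labels mRNA was isolated with Dynabeads, so RNAs without a poly(A) tail, such as those of replication-dependent histones and small noncoding RNAs, may be captured in part. No spike-in rows stand in the table, the scaling steps are not given in the sources used here, and values carry 1 decimal, so read depth is unknown. Their totals were 1015232 and 1040749 in shCtl and 687051 and 681178 in shWDR43. The authors also deposited a signed fold change of group means and an unadjusted p-value for 23520 genes, with 15062 left empty and none above 0.5, and its test is not given in the sources used here.

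Gene expression was compared with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(FPKM + 1) of the 12452 genes with a mean FPKM of at least 1. These were 32.3% of all genes. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p under 0.05. Fold changes on this scale understate the change of genes with low values. No scaling was added to the deposited spike-in scale. The fit was tested on simulated data made from the same 12452 genes with 50 genes changed at each size. It recovered 4% of 1.5-fold, 36% of 2-fold, 76% of 4-fold and 96% of 8-fold changes, with 3 false calls. In the data far more genes (6082) passed, which eases the adjusted threshold, so these shares do not give the recovery there. For 18 gene lists fixed before the data were examined, limma's fry tested whether a list moved one way, and camera, with a preset correlation of 0.01 and then an estimated one, compared it with other genes. Percentiles of list medians among 10000 random lists matched on mean expression, and differences within 5 bins of expression for genes with and without peaks, were added after the data were seen.

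The genes named in the text follow a rule set before the data were examined. Wdr43 came first, then the 10 largest rises and 10 largest falls among genes past the threshold with both shWDR43 libraries outside the shCtl range, then the 2 highest and 2 lowest members of each list. Some genes that this rule picks are left out of the text. For peaks, the 3 regions with the highest score per set were taken, with ties, many of them at a score of 3100, broken by width. Names and loci came from the deposited table. Its loci were read as 0-based starts on mm9 and are printed 1-based, as are peaks. The table gives no strand or exons, so peaks were placed at either end of a protein-coding locus (within 1 kb), inside it, or outside. RNA counting was not stated to use strand, so overlapping and antisense loci and near-identical copies are uncertain.

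Peaks overlapped when they shared at least 1 bp. Consensus peaks of a Pol II group were peaks of its library 1 that overlapped a peak of library 2. A gained peak was a shWDR43 consensus peak with no peak in either shCtl library, and a lost peak the reverse. Overlaps were set against 100 random placements within chromosomes. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Pol II peak numbers were compared by an exact two-sided permutation test, where 2 against 2 libraries allow no p below 0.333. Fold changes of genes with and without peaks were compared by two-sided permutation tests with 100000 label shuffles over genes, which are not independent replicates, so these p-values describe the gene sets of these libraries. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used, and the overlap and permutation code was tested on known intervals and simulated values.

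Alternatives set before the data were examined covered the pseudocount, the filter on low values, a replicate block, median-centred libraries, the intensity trend, a 1.5-fold limit, each library left out in turn, stricter or merged peaks, other overlap rules, other WDR43 peaks and extended loci.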

Results

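The data comprised 5 WDR43 peak lists from FLAG-tagged mouse embryonic stem cells, 12 Pol II peak lists and 4 RNA libraries. WDR43 was mapped in cells treated with the solvent DMSO, with DRB (an inhibitor of the kinase that releases paused Pol II) or with actinomycin D (ActD, a DNA intercalator that blocks transcription), each in 1 library. It was also mapped in 1 library of FB-tagged cells and 1 of a cFB knock-in. Pol II was mapped in 2 shCtl and 2 shWDR43 libraries each with antibody 8WG16 (hypoP, hypophosphorylated Pol II), with one against serine 5 phosphorylation (Ser5P, enriched near starts of genes) and with one against serine 2 phosphorylation (Ser2P, enriched in elongating Pol II). The nature of the ChIP replicates is not stated, so their spread may be technical, or include more than 1 hairpin. Read depth is unknown for all libraries.

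In shWDR43 the RNA of Wdr43 was lower, and the median RNA was lower too on the spike-in scale, which cannot be checked here for an offset shared by all genes. Wdr43 (NM_175639, chromosome 17, 71965555 to 72008371, mm9) stood at 82.3 and 78.2 FPKM in shCtl and at 21.2 and 20.7 in shWDR43. Its mean fell from 80.2 ± 2.90 to 20.9 ± 0.354 (SD, n = 2 each), 3.83-fold, with a log2 fold change of -1.89 ± 0.12 (SE, limma, Benjamini-Hochberg adjusted p = 0.000751). Of 12452 tested genes, 5322 (42.7%) were lower and 760 higher in shWDR43. The median log2 fold change was -0.39, with quartiles of -0.71 and -0.06, and 78.1% of genes lay below 0. The 4 differences between single shWDR43 and shCtl libraries had medians from -0.48 to -0.31, against -0.05 between the shCtl libraries and -0.13 between the shWDR43 libraries. Highly expressed genes fell most: over 5 equal bins of expression the median went from -0.16 in the lowest to -0.69 in the highest. Transcripts of the mitochondrial genome, made by a separate polymerase, were lower at 7 of 9 loci, with a median of -0.99. With libraries centred on their median, a shift of 0.33 for each gene, 2606 genes were lower and 1615 higher, so lower genes made 61.7% of calls in place of 87.5%. All 760 higher genes and 2606 of the lower genes of the spike-in scale were shared. Leaving out any of the 4 libraries ended every call in limma, with 1 residual degree of freedom. At an unadjusted p under 0.05 those fits held 576 to 730 higher and 3928 to 4902 lower genes, and all called genes kept their sign.

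**Figure D1:**
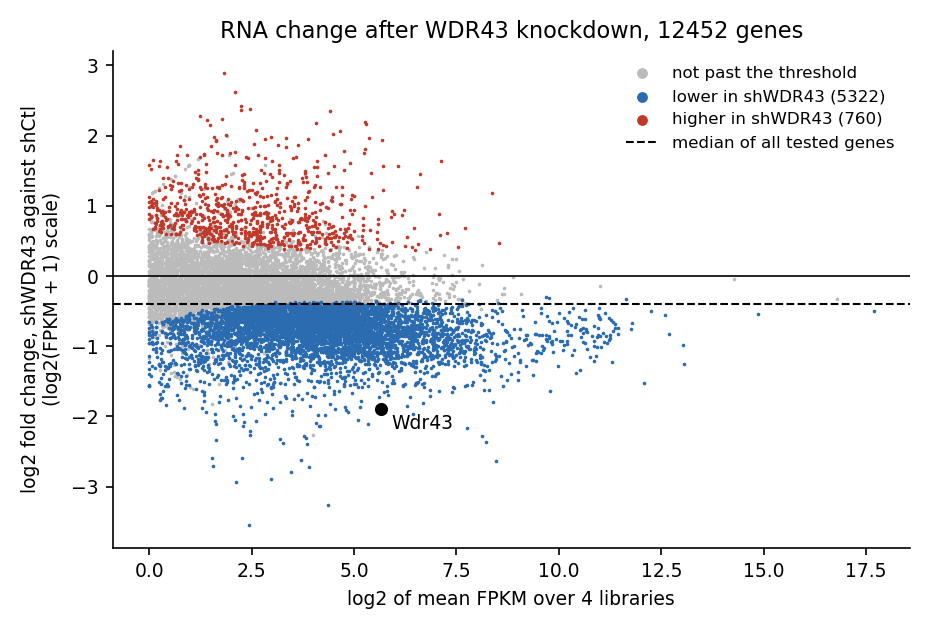
Log2 fold change of shWDR43 against shCtl on the log2(FPKM + 1) scale, plotted against the log2 of mean FPKM, 1 point per tested gene (2 libraries per group). Blue points (5322) were lower and red points (760) higher at an adjusted p under 0.05, and the dashed line marks the median of -0.39, below 0.

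Genes of pluripotency and of ribosome production fell together. In the naive pluripotency list, 26 of 32 genes were lower and 0 higher, with a median log2 fold change of -0.80. Tdgf1, a Nodal co-receptor, fell from 354 ± 0.0707 to 78.7 ± 11.8 FPKM (SD, n = 2 each; log2 fold change -2.16), and Tcl1 fell by 1.72 on the log2 scale. Tbx3 (-0.21) and Fbxo15 (0.24) did not pass, and Fbxo15 was higher after centring (0.57). Of the small-subunit processome, the nucleolar assembly to which WDR43 belongs, 32 of 35 genes were lower, with a median of -0.84. Nhp2l1 (-1.21) and Mphosph10 (-1.15) fell most, and Pwp2 (-0.01) and Utp20 (-0.04) did not pass. Of the Pol I and nucleolar list, 34 of 36 genes were lower, with a median of -0.86, led by Nolc1 (-1.53) and Ncl (-1.48), nucleolar phosphoproteins, while Taf1c (-0.34) did not pass and Polr1e (-0.38) did. All 78 cytosolic ribosomal protein genes were lower, with a median of -0.83, from Rpl3 (-1.28) and Rps24 (-1.22) to Rps19 (-0.46). Relative to the shift of all genes, the medians of these 4 lists were -0.47, -0.51, -0.53 and -0.50. After centring, 18, 26, 27 and 62 of their genes were still lower, and 1 pluripotency gene was higher. Random lists matched on expression had a median of -0.84 for the ribosomal proteins, which lay at the 55.5th percentile, so no larger fall than in matched lists was seen. The draws came from 20 equal bins of expression that included the list itself, so the match is coarse for such abundant genes. The pluripotency list lay at the 5.40th, the processome at the 0.480th and the Pol I list at the 0.280th percentile.

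Many targets of p53 rose against this general fall. Of 34 tested genes, 17 were higher, 1 was lower and 16 did not pass. Their median log2 fold change was 0.43, or 0.76 relative to the shift. Fry called the list upward (adjusted p = 0.0221). Camera with an estimated correlation did not set it apart from other genes (adjusted p = 0.339), but that mode had little power with 4 libraries. Perp, a desmosomal p53 target of apoptosis, rose from 13.7 ± 2.05 to 65.0 ± 13.7 FPKM (SD, n = 2 each; log2 fold change 2.16) and Dcxr from 8.30 ± 0.424 to 36.6 ± 0.566 (2.02). Cdkn1a, the cell cycle inhibitor p21, rose by 1.52 and Mdm2, the ubiquitin ligase of p53, by 1.46 on the log2 scale (both named after their values were seen). Rps27l (-0.30) was lower, although 0.03 after centring, and Ddb2 (-0.40) did not pass. The call of Rps27l ended with the replicate block and without the intensity trend. Of 26 markers of mesoderm and endoderm only 9 were tested, and of these 4 were higher and 0 lower, with a median of 0.42. The tested ones were Col4a1, Col4a2, Lama1, Lamb1, Sparc, Dab2, Gata4, Gata6 and Eomes, so most of the list was not measured. Basement membrane collagens Col4a2 (1.17) and Col4a1 (0.97) led, and Lamb1 (0.11) and Eomes (-0.55) did not pass. Of 17 trophectoderm genes 10 were tested, with 4 higher, 1 lower and a median of 0.35. Epithelial keratins Krt19 (1.28) and Krt7 (1.27) led, Tead4 (-0.57) was lower and Eomes did not pass. Markers of fibroblasts, which can serve as feeder cells, were higher for 4 (7 with the replicate block) and lower for 2 of 17, with a median of 0.43. Tagln (1.32) and Timp3 (1.02) rose, and Thy1 (-1.35) and Fn1 (-0.47) fell. In this list Col3a1 stood at no more than 0.7 FPKM in any library, while Col1a1 stood at 12.3 and 18.4 in shCtl and at 17.9 and 30.9 in shWDR43.

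Stress and early response genes went both ways. In the ATF4 list, 12 of 22 genes were lower and 3 higher, with a median of -0.80. The stress regulators Ddit3 (1.70) and Ddit4 (1.61) rose, while Chac1 (-2.11) and Psat1 (-1.53), a serine synthesis enzyme, fell. Of 14 immediate early genes, 5 were higher and 4 lower, with a median of 0.36. The matricellular genes Cyr61 (2.06) and Ctgf (1.55) rose, and Myc (-2.31) and Dusp6 (-1.08) fell. Of 22 genes of the 2-cell-like state, 6 were higher and 1 lower, with a median of 0.39 (Tdpoz3 at 1.04, Gm6763 at 0.81, not past the threshold, Tcstv1 at -0.67, not past it, and Eif1a at -0.72). The number higher was 12 with the replicate block. These form near-identical families and are uncertain. Cholesterol synthesis genes were lower for 21 of 23, with a median of -0.75 (Idi1 -1.44, Fdps -1.14), while Mvk (0.13) and Stard4 (-0.29) did not pass. Of 28 interferon response genes only 8 were tested, and 5 of these were lower, with a median of -0.67 (Ddx58 -1.37, Bst2 -1.22), while Stat2 (-0.11) did not pass. G2 and M cell cycle genes were lower for 20 of 25, with a median of -0.68 against -0.66 for matched lists, so they fell as far as others of their abundance (Mad2l1 -1.12, Ccna2 -1.07), while Hmmr (-0.18) and Cenpe (-0.21) did not pass. Of 20 neuroectoderm genes 13 were tested, with 6 lower, 1 higher and a median of -0.31. Gbx2 (-1.87) and Pou3f1 (-1.12) fell, and Nefm rose (0.73), a call that ended with the replicate block.

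Most genes of the Pol II machinery were lower on the spike-in scale. Of 13 Pol II subunit genes, 11 were lower, with a median of -0.86, led by Polr2i (-1.19) and Polr2k (-1.18). The largest subunits Polr2a (0.12) and Polr2b (-0.10) did not pass, and 1 subunit gene was higher after centring. The subunit median lay at the 11.8th percentile of matched lists. Of 31 pause and elongation genes, 20 were lower, with a median of -0.52 against -0.55 for matched lists. Ssrp1 (-1.14) and Supt16 (from 167 to 82.7 FPKM), the subunits of the histone chaperone FACT, fell most, while Ell3 (0.23) and Ell (0.07) did not pass. Replication-dependent histone genes split into 13 higher and 10 lower of 47. Their median was 0.26, their mean 0.05 and their summed FPKM 1056 in shCtl and 595 in shWDR43. Abundant members such as Hist1h2ad (-1.71), as well as Hist1h2ak (-1.85), fell. Hist1h2bb (1.46) and Hist1h3g (1.07) had the highest values and did not pass, and copies of these genes are nearly identical. Their RNAs lack the poly(A) tail by which mRNA is commonly isolated, which limits these values.

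In camera with the preset correlation, 14 of 18 lists passed at a Benjamini-Hochberg adjusted p under 0.05. The adjusted p was 4.28e-05 for pluripotency, 4.02e-05 for the processome, 1.15e-06 for Pol I, 5.75e-16 for ribosomal proteins and 6.90e-19 for p53 targets, and the neuroectoderm (0.729), pause (0.0629), interferon (0.341) and ATF4 (0.637) lists missed. Camera called no list once the correlation was estimated. In that mode it tests on the few residual degrees of freedom of the 4 libraries, so a missed call says little. The mesoderm and trophectoderm lists missed too, although their estimated correlations (0.0136 and -0.0450) lay near or below the preset 0.01. Adjusted p = 0.415 with an estimated correlation for pluripotency, adjusted p = 0.590 with an estimated correlation for the processome, adjusted p = 0.531 with an estimated correlation for the Pol I and the Pol II subunit lists, and adjusted p = 0.339 with an estimated correlation for the p53, mesoderm and trophectoderm lists. The histone list gave adjusted p = 0.344 and the G2 and M list adjusted p = 0.613 with an estimated correlation. For ribosomal proteins and for the 2-cell-like, immediate early, cholesterol and fibroblast lists, adjusted p = 0.524 with an estimated correlation. In fry, which does not compare a list with other genes, 13 lists passed, while the 2-cell-like (0.202), immediate early (0.201), fibroblast (0.202), histone (0.810) and G2 and M (0.0711) lists did not. Camera placed the histones upward and fry downward, and camera placed the neuroectoderm list upward against a median below 0. Adjusted over the list alone, the counts of lower genes were 28 for pluripotency, 32 for the processome, 35 for Pol I, 78 for ribosomal proteins, 22 for pause and elongation, 22 for G2 and M, and 11 for subunits. The other lists held, adjusted over the list alone, 18 higher and 1 lower for p53 targets, 7 and 5 for immediate early, 1 and 1 for the 2-cell-like state, and 4 and 2 for trophectoderm. The remaining 7 lists kept their counts when adjusted over the list alone.

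How many genes of a list were called depended on the scale and on the filter. Without the filter on low values fewer genes of every list were called. Lower genes then numbered 21 for pluripotency, 13 for the processome, 21 for Pol I, 70 for ribosomal proteins, 8 for pause and elongation, 8 for Pol II subunits, 13 for cholesterol synthesis and 5 for G2 and M. Higher and lower genes numbered 13 and 0 for p53 targets, 3 and 0 each for the mesoderm and the trophectoderm list, 2 and 1 for fibroblasts and 0 and 0 for the 2-cell-like state. They numbered 2 and 11 for ATF4, 4 and 2 for immediate early, 1 and 3 for interferon and 0 and 4 for neuroectoderm genes. Histone genes turned to 2 higher and 5 lower. After centring, higher and lower genes numbered 26 and 0 for p53 targets, 7 and 0 for mesoderm, 5 and 0 for trophectoderm, 7 and 1 for fibroblasts, 16 and 1 for the 2-cell-like state, 8 and 3 for immediate early and 17 and 8 for histone genes. They numbered 1 and 11 for cholesterol synthesis, 0 and 9 for G2 and M, 2 and 9 for pause and elongation, 1 and 10 for subunits, 4 and 10 for ATF4, 1 and 2 for interferon and 2 and 5 for neuroectoderm genes. The cause of the drop without the filter was not tested.

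**Figure D2:**
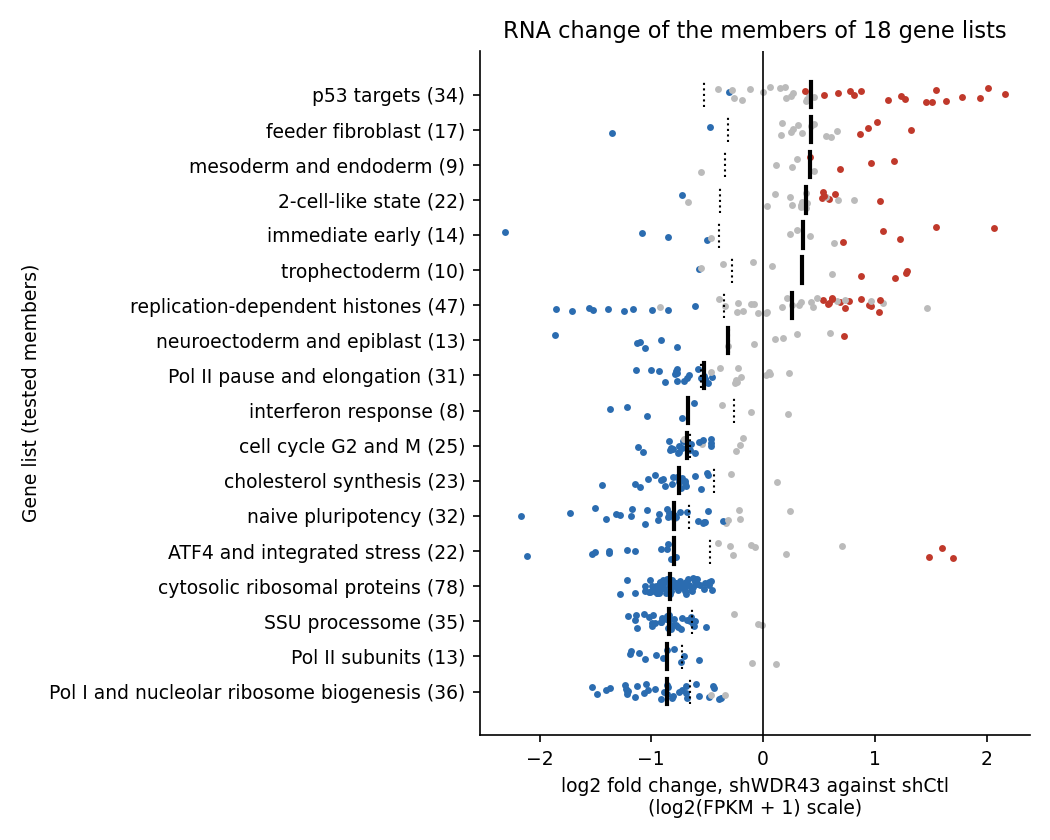
Log2 fold change of shWDR43 against shCtl on the log2(FPKM + 1) scale for each tested member of 18 gene lists (rows, number of members in parentheses). Red and blue points were higher and lower at an adjusted p under 0.05, solid bars are list medians and dotted bars the medians of expression-matched random lists. The p53 list lies at 0.43 against a matched median of -0.53.

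The largest single changes included signalling genes. Lefty2 (NM_177099, chromosome 1, 182823250 to 182829233), an antagonist of Nodal, fell from 38.3 ± 3.39 to 3.10 ± 0.141 FPKM (SD, n = 2 each), a log2 fold change of -3.26 ± 0.14 (SE, limma, Benjamini-Hochberg adjusted p = 0.000717). Its near-identical neighbour Lefty1 fell by 2.71 on the log2 scale, and reads of the copies may be shared. Fgf15 (-2.90), a secreted growth factor, Myrf (-2.79), a transcription factor, the lactate carrier Slc16a3 (-2.61), Hopx (-2.59) and the unnamed locus XLOC_015739 (-2.63) also fell. AK219036 (inside Tbc1d22a), XLOC_023682 and XLOC_001314 were listed at 0 in both shWDR43 libraries. Among the largest rises were the leukotriene B4 receptors Ltb4r1 (2.42) and Ltb4r2 (2.37), neighbours on chromosome 14. Rtkn (NM_001136227, chromosome 6, 83085802 to 83102573) rose from 6.30 ± 0.424 to 36.6 ± 6.43 FPKM, a log2 fold change of 2.35 ± 0.16 (SE, adjusted p = 0.000802). Gpx3 (2.19), a secreted glutathione peroxidase, Cpz (2.23), Sytl1 (2.22) and XLOC_017348 (2.37) rose too. Scarna13, inside Snhg10, was listed at 0 in both shCtl libraries and at 10.4 and 3.8 FPKM in shWDR43, and XLOC_023869 at 0 and then at 1.7 and 7.8. In the authors' deposited table, 4609 genes were at least 1.5-fold lower and 1259 higher with an unadjusted p under 0.05.

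The inhibitor comparison asked where WDR43 was found when transcription was blocked, and far fewer WDR43 peaks were called under both inhibitors. The DMSO library held 31189 peaks over 8.96 Mb, DRB 4426 peaks over 0.993 Mb and ActD 407 peaks over 0.181 Mb. These were 14.2% (DRB) and 1.30% (ActD) of the DMSO number, and not all lay at DMSO peaks: 2919 of the DRB peaks (66.0%) and 319 of the ActD peaks (78.4%) did. Of the DMSO peaks, 9.30% (95% interval 8.98 to 9.63) overlapped a DRB peak and 1.01% (0.905 to 1.13) an ActD peak. Among the tenth with the highest scores, 31.2% (29.5 to 32.8) overlapped a DRB peak and 7.31% (6.42 to 8.28) an ActD peak. Peaks at ends of protein-coding loci were kept under DRB as often as others, making 34.1% of kept and 33.8% of other DMSO peaks. Under ActD they made 15.2% of kept peaks, against 33.8% of all DMSO peaks. In all 3 conditions a peak with a score of 3100 covered Rn45s (chromosome 17, 39979942 to 39985774), the annotated copy of the 45S ribosomal RNA precursor. The next ActD peaks lay at Erich1 on chromosome 8, also second under DRB, and at chromosome 9, 21754732 to 21755257, outside named loci. Rn45s held a peak in all 17 lists, Pol II included, and 35 of the 407 ActD peaks (8.60%) lay at a peak in each of the other 16 lists. The tested treatments had 1 library each, so no replicate spread can be set against these differences, and depth and enrichment per library are unknown.

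**Figure D3:**
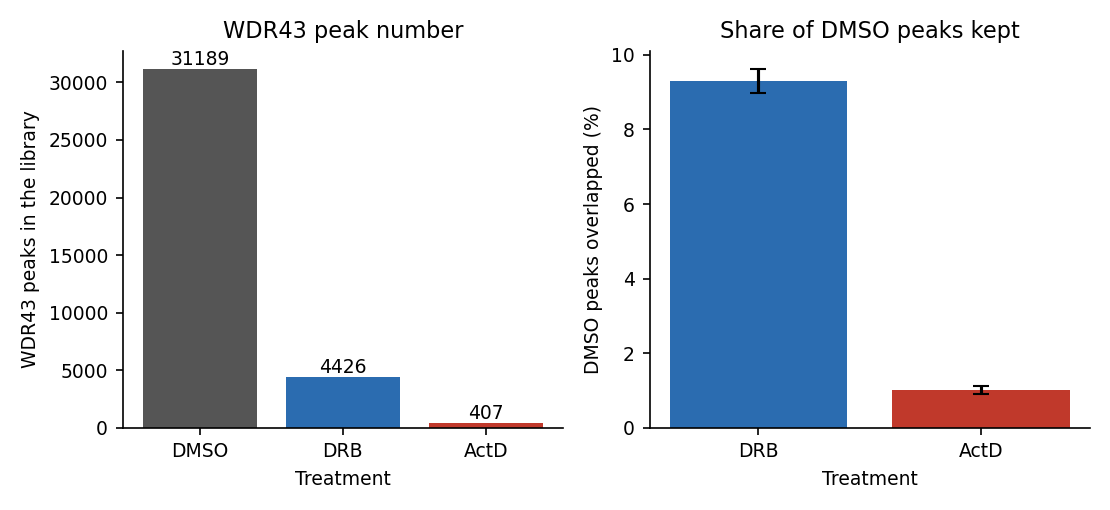
Number of WDR43 peaks in the DMSO, DRB and ActD libraries (left, 1 library each) and the percentage of the 31189 DMSO peaks that overlapped a peak under each inhibitor (right, bars with exact 95% binomial intervals for counting error only). The DRB library held 4426 and the ActD library 407 peaks.

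WDR43 occupied ends of protein-coding loci, and its separate maps overlapped. The FB map held 41552 peaks with a mean width of 419 bp, and the cFB knock-in 21553 peaks with a mean width of 1151 bp. At ends of coding loci lay 35.6% of FB, 53.2% of cFB and 33.8% of DMSO peaks, against 3.49%, 4.61% and 3.30% of randomly placed ones. Of cFB peaks, 73.2% (72.6 to 73.8) overlapped an FB peak, against 2.42% by chance, and of DMSO peaks 70.3% (69.8 to 70.8), against 1.14%. The reverse shares of FB peaks were 47.6% at cFB and 48.1% at DMSO peaks. Of the cFB peaks 57.3% lay at DMSO peaks, and of the DMSO peaks 49.2% at cFB peaks. Scores of 3100 recur in most lists as if capped, so the highest regions named here are close to ties. The highest FB scores were at chromosome 6, 47721698 to 47723253, at Rn4.5s on the same chromosome and at Rn45s. The highest cFB scores were at Aida on an unplaced part of chromosome 1, at Cdk8 and at Cmss1 with Filip1l. The Cdk8 locus, like Rn45s, held a peak in all 17 lists, Pol II and ActD included, so it is not particular to WDR43. In DMSO, C230081A13Rik on chromosome 9 and an unplaced sequence scored highest with Rn45s. Of tested genes, 80.6% carried an FB peak within the locus. The shares were 47 of 47 for the histone list, 76 of 78 for ribosomal proteins, 34 of 35 for the processome, 31 of 34 for p53 targets and 26 of 32 for pluripotency. Only 2 of 22 genes of the 2-cell-like list and 9 of 17 of the fibroblast list carried one. The 2-cell-like genes form near-identical families, where reads may go unplaced. A peak was also less common at low expressed genes. In the lowest of 5 expression bins 1594 genes carried one and 897 did not, against 2207 and 283 in the highest.

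Many WDR43 peaks lay at hypophosphorylated Pol II, and most hypoP and Ser5P consensus peaks carried a WDR43 peak. Of the 17924 hypoP consensus peaks of shCtl, 80.8% (80.2 to 81.4) carried an FB peak, and of FB peaks 45.5% (45.0 to 46.0) lay at a hypoP peak, against 1.51% by chance. Of the 731 Ser5P consensus peaks 84.4% (81.6 to 87.0) carried an FB peak, and of the 2901 Ser2P consensus peaks 46.5% (44.6 to 48.3). The small Ser5P and Ser2P lists took up 1.79% and 4.36% of FB peaks, against 0.0392% and 0.348% by chance. Random placement did not keep the enrichment of peaks at ends of coding loci, so overlap beyond that shared enrichment was not tested. For cFB peaks the shares at hypoP, Ser5P and Ser2P were 57.1%, 2.99% and 5.08%, and for DMSO peaks 48.9%, 2.64% and 4.39%. The Ser5P share of FB peaks rose to 5.83% without shCtl library 1 and to 4.33% without library 2, since a single library then stood for the consensus.

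Pol II peaks changed in opposite directions between forms after WDR43 knockdown. Ser5P peaks numbered 2200 ± 453 in shCtl and 7062 ± 745 in shWDR43 (mean ± SD, n = 2 each), a ratio of 3.21. HypoP peaks numbered 19552 ± 13.4 and 27979 ± 4941, a ratio of 1.43, and Ser2P peaks 4098 ± 312 and 3502 ± 2.12, a ratio of 0.855. Every shWDR43 library lay above both shCtl libraries for Ser5P and hypoP and below both for Ser2P. The exact permutation p was 0.333 for each form (n = 2 each), the smallest this design allows. Depth per library is unknown, and the labels of the hypoP groups differ in detail, so these numbers may also reflect how libraries were made. Mean peak width rose from 774 to 1030 bp for Ser5P and fell from 2381 to 2121 bp for Ser2P. It was 1739 and 1760 bp for hypoP, a difference within the spread of its libraries. Covered length rose from 1.70 to 7.27 Mb for Ser5P and 1.45-fold for hypoP, and fell from 9.77 to 7.43 Mb for Ser2P.

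Most control consensus peaks of hypoP and Ser5P were also called after knockdown, and further peaks were called only there. Gained peaks had lower median scores than shared ones (158 against 566 for hypoP, 72.5 against 92.7 for Ser5P). Depth is unknown, so a gained peak may have been present in shCtl below the threshold of the caller. The consensus held 91.7% of the peaks of shCtl library 1 for hypoP but only 38.9% for Ser5P. Of the 2934 shCtl Ser5P peaks called in 1 library alone, 29.2% lay at shWDR43 consensus peaks. Of Ser5P consensus peaks in shWDR43, 2424 of 3800 (63.8%, 62.2 to 65.3) were gained, and 96 of 731 shCtl peaks (13.1%, 10.8 to 15.8) were lost. For hypoP, 4423 of 23688 (18.7%) were gained and 139 of 17924 (0.775%) lost. For Ser2P, 222 of 2465 (9.01%) were gained and 480 of 2901 (16.5%) lost. Gained hypoP peaks lay at ends of coding loci in 16.5% of cases and inside loci in 30.8%, against 50.8% and 13.0% of shared peaks, and 27.0% carried an FB peak, against 79.4%. Gained Ser5P peaks carried one in 69.3% of cases, against 90.2% of shared ones. Of lost Ser2P peaks 28.1% carried one, against 52.8% of shared ones. The highest gained Ser5P peak lay at Rpl41 and Zc3h10 (chromosome 10, 127984189 to 127986649), followed by Gm17692 and a region of chromosome 5. The highest lost ones lay at Il6ra, 9030025P20Rik and Eif4a2. Gained hypoP peaks were highest on chromosome 12 outside named loci, at Zfp41 and at Map3k7. Lost hypoP peaks were highest at Cirbp, at a histone cluster with Hist1h2ai, Hist1h2bl and Hist1h3h, and at Terc, the telomerase RNA. Gained Ser2P peaks were highest at Ptma, Pkm and Msh4 with Rabggtb, and lost ones at Mog with Zfp57 and on chromosomes 3 and 1 outside named loci. Shared peaks scored highest at Eapp and Rn45s (hypoP) and at Cdk8 (Ser5P), and otherwise outside named loci. With any of the libraries left out, a single library stood for its group and counts ranged from 4882 to 11193 gained and 299 to 444 lost for hypoP, 2760 to 5639 and 135 to 863 for Ser5P, and 404 to 735 and 739 to 1398 for Ser2P. Without either shWDR43 Ser2P library the gained and lost numbers were close (708 and 739, 735 and 766), so the excess of losses rests on the consensus of both. Peaks above the median score of each list gave fewer of each.

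**Figure D4:**
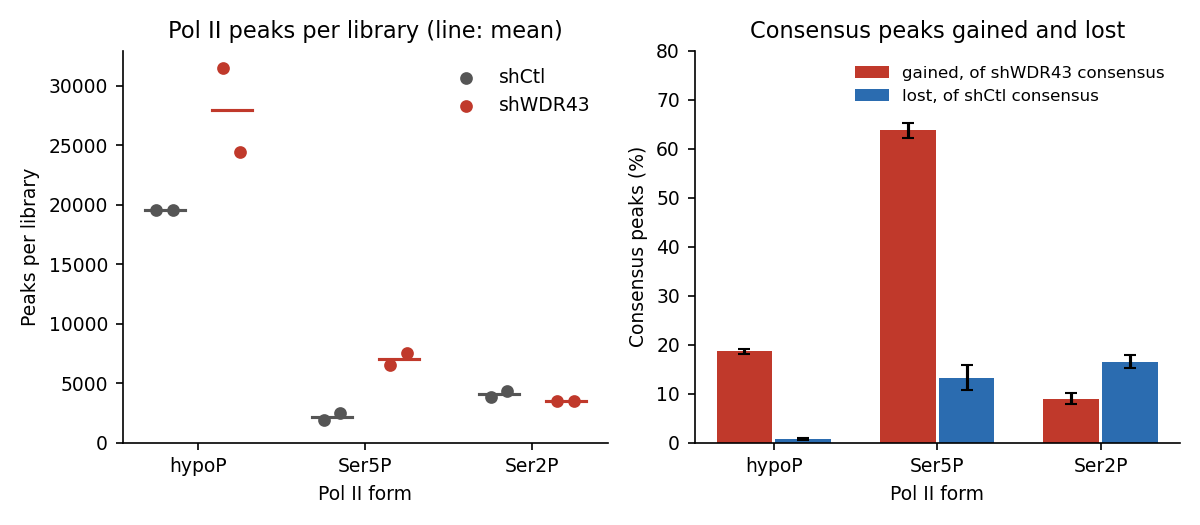
Number of Pol II peaks per library for the hypoP, Ser5P and Ser2P forms in shCtl and shWDR43 (left, points are libraries, lines are means) and the percentage of consensus peaks gained or lost in shWDR43 (right, with exact 95% binomial intervals for counting error only). Ser5P and hypoP peaks were more numerous in shWDR43 (ratios 3.21 and 1.43) and Ser2P peaks fewer (0.855).

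The median RNA of genes that gained hypoP peaks fell less than that of genes with shared peaks. The 1234 tested genes with a gained hypoP peak in the locus had a median log2 fold change of -0.18, against -0.42 for 9393 genes with shared peaks and no gain or loss. The difference was 0.25 (permutation p = 1e-05, the smallest the shuffles can give, Benjamini-Hochberg adjusted p = 3.5e-05 over 7 comparisons) and 0.16 within bins of expression. Of these genes 13.2% were higher in shWDR43, against 4.65%, but so were 12.2% of the 82 genes at lost hypoP peaks, so a raised share was not particular to gains. Named genes among them went both ways, with Rtkn, Cpz, Sytl1, Krt19, Dcxr and Tagln higher and Dusp6 and XLOC_023682 lower. Genes at gained Ser5P peaks (1372) did not stand apart from the 1052 at shared ones, with a difference of 0.01 (permutation p = 0.64, adjusted 0.89), nor did those at lost Ser5P (0.02, p = 0.78, adjusted 0.90), gained Ser2P (0.00, p = 0.90, adjusted 0.90) or lost hypoP peaks (-0.11, p = 0.075, adjusted 0.13) in permutation tests. Within expression bins the difference at lost hypoP peaks turned to 0.04, with bins on both sides of 0. The 227 genes at lost Ser2P peaks fell further, by a difference of -0.09 (permutation p = 0.035), which did not hold over the 7 comparisons (adjusted p = 0.081). Within expression bins the difference at lost Ser2P peaks was -0.11.

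Genes with a WDR43 peak fell slightly further than genes without. The 10031 genes with an FB peak in the locus had a median log2 fold change of -0.41 and the 2421 without of -0.34, a difference of -0.06 (permutation p = 1e-05, adjusted p = 3.5e-05). Within 5 equal bins of mean expression the differences ran from -0.01 to 0.04, with a weighted mean of 0.02, and none reached a permutation p under 0.05 (lowest 0.10). With cFB peaks the difference was -0.01 (permutation p = 0.59) and at a mean FPKM of at least 5 it was -0.02 (permutation p = 0.36), so the call ended in both.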

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

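Among the tests below, those of the RNA patterns were chosen after the results were seen, and those of the Ser5P and hypoP peaks were set before. The forms of Pol II moved apart: in every shWDR43 library peak numbers lay above both shCtl libraries for hypoP (ratio 1.43) and Ser5P (3.21) and below both for Ser2P (0.855). The difference between forms was not tested.

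More sensitive peak calling in the shWDR43 libraries, through depth or enrichment, may account for the Ser5P and hypoP peak numbers. It would find peaks that were marginal in shCtl, and 29.2% (27.6 to 30.9) of the 2934 shCtl Ser5P peaks called in 1 library alone lay at shWDR43 consensus peaks, against 0.299% by chance, a value between the bounds set beforehand, so the cause stays open without read depth. For hypoP the same share, looked at after, was 62.3%, in line with higher sensitivity in shWDR43, and the labels of the hypoP groups differ in detail, so they may have been handled apart. The mark of sensitivity set beforehand was that genes at gained hypoP peaks would differ little from genes with only weak shared peaks. Genes at gained peaks (1234) instead stood 0.21 higher in log2 fold change, within expression bins, than 562 genes with only weak shared peaks (permutation p = 1e-05). The difference was 0.33 with strong shared peaks barred from both sets (429 genes, added after). Yet loci whose RNA fell less could cross a threshold first, so this difference cannot decide on sensitivity. Gained hypoP peaks also lay inside coding loci more often than shared ones (30.8% against 13.0%). Gained Ser5P peaks showed no link to RNA (difference 0.01, permutation p = 0.64). For the peak numbers, an effect of WDR43 knockdown stays among the open explanations.

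Most RNAs were lower in shWDR43 on the spike-in scale. With 0 spike-in rows in the table, an offset of the spike-in scaling shared by all genes cannot be told apart from a fall of RNA per cell, and mitochondrial RNAs fell too (median -0.99). An offset does not account for the larger fall at highly expressed genes: with a pseudocount of 0.1 the difference of medians between the highest and the lowest of 5 expression bins was -0.455. The most abundant RNA, XLOC_014354 on chromosome 3, held 24.0% and 23.7% of summed FPKM in shCtl and 24.8% and 26.2% in shWDR43. That change in share allows a change of the rest of -0.0304 on the log2 scale, which explains little. Shares of FPKM are not shares of reads, which are unknown here. A lower RNA content after knockdown stays open.

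The medians of the fibroblast, mesoderm and trophectoderm lists rose, although 4 genes of each were called higher. Only 9 of the 26 mesoderm and endoderm genes were tested. Fry missed the fibroblast list (adjusted p = 0.202), and the neuroectoderm list did not rise. RNA of feeder fibroblasts would bring their abundant transcripts, and the highest of Col3a1, Dcn, Lum and Postn in shWDR43 reached 2.87% of the Col1a1 mean. These genes were picked from the list after its values were seen. Other members were present in shWDR43, such as Col1a2 (16.4 and 28.8 FPKM) and S100a4 (79.9 and 117.9). So these values cannot settle that source. Against a smaller fall of all low expressed genes, the fibroblast, mesoderm and trophectoderm medians lay at the 99.8th percentile or above of random lists matched on expression. Those draws treat genes as independent, while fibroblast genes moved together (estimated correlation 0.684). The correlations estimated for mesoderm (0.0136) and trophectoderm (-0.0450) were small. Camera with an estimated correlation called none of these lists (adjusted p = 0.524 for fibroblasts, 0.339 for mesoderm and for trophectoderm). That mode had little power with 4 libraries. So a smaller fall of low expressed genes is not excluded for the fibroblast list. The percentiles argue against it for the mesoderm and trophectoderm lists, of which only 9 and 10 genes were tested. Feeder RNA, a change in the stem cells themselves after knockdown, or an off-target effect of the hairpin may remain. None was tested beyond these values.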

How the results depend on the processing

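RNA directions depended on scale more than on other settings. Genes higher and lower numbered 402 and 2593 without a filter on low values (median log2 fold change -0.14), 472 and 4885 at a mean FPKM of at least 5 (median -0.50), and 1615 and 2606 in median-centred libraries (median -0.0642, by construction near 0). With the replicate block, 840 genes were higher and 5926 lower (760 and 5322 without), the median was -0.39 and 15 lists passed. Counts of lists in this section are from camera with the preset correlation, and on the main settings none passed with an estimated one. Over all tested genes same-numbered libraries deviated together little (correlation 0.0504), so the main fit did not take the numbers as pairs. Yet the block raised both counts of calls while using up a residual degree of freedom. A replicate effect shared by some genes is thus not excluded. Each library left out gave 0 to 0 calls, 12 to 15 lists and medians from -0.45 to -0.34. Rps27l turned to 0.0274 after centring. Rescaling on spike-in rows was not run, as the table holds none, nor was a count model, as it holds no counts.
Peak settings moved values little in direction. Merging peaks within 1 kb gave 14.9% (DRB) and 1.45% (ActD) of the DMSO number and shares kept of 10.1% and 1.14%. Peaks above the median score kept 1.14% under ActD. Requiring 50% of the shorter peak kept 8.34% under DRB, and counting peaks within 1 kb kept 13.4% and 1.20%. For cFB at FB peaks above the median score gave 80.3% and the 1 kb rule 74.7%, and for DMSO at FB merging gave 69.2%, the 50% rule 67.3% and the 1 kb rule 74.7%. FB shares at hypoP, Ser5P and Ser2P were 42.2%, 1.64% and 3.43% above the median score, 44.9%, 1.59% and 4.13% with the 50% rule, and 47.8%, 2.21% and 5.29% with the 1 kb rule. Merged peaks gave 42.6% at hypoP and 4.06% at Ser2P. Without 1 library they ranged from 47.6% to 47.9%, 4.33% to 5.83% and 5.47% to 6.09%. Gained and lost peaks above the median score numbered 2044 and 48 (hypoP), 1187 and 35 (Ser5P) and 124 and 278 (Ser2P). Without 1 library they ranged from 4882 to 11193 and 299 to 444, 2760 to 5639 and 135 to 863, and 404 to 735 and 739 to 1398. Pol II number ratios ranged from 1.25 to 1.61, 2.80 to 3.76 and 0.811 to 0.903 without 1 library, and the replicate block gave 1.43, 3.25 and 0.857. The difference by WDR43 binding was -0.00708 with cFB peaks and -0.0168 at a mean FPKM of at least 5. At lost hypoP peaks an unadjusted p under 0.05 appeared with loci extended by 1 kb (-0.12), and at lost Ser2P peaks it was gone with extended loci (-0.0463) and at a mean FPKM of at least 5 (-0.0588), neither of which was a call over the 7 comparisons. Fewer peaks or genes entered the stricter settings. The cause of the other moves was not tested. Of 1295 alternative values over 149 results, 862 stayed the same, 314 grew weaker, 107 moved, 11 grew stronger and 1 reversed. Unknown read depth limits all peak numbers.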

Other observations

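The gene groups by symbol (21 tried, 18 of them with enough genes) and the test of WDR43 binding within expression bins were chosen after the data were seen, and the test of locus length was set before its result. Some of these symbol groups fell further than random lists matched on expression and others did not. Collagen genes went the other way, with 6 higher and 0 lower of 14 (median 0.64, matched -0.32). So did keratin genes, with 3 higher and 1 lower of 7 (median 0.62, matched -0.22). Of 17 genes for tRNA synthetases 16 were lower in shWDR43, with a median log2 fold change of -0.99 against -0.67 for random lists matched on expression. Vars (-1.27) and Yars (-1.15) fell, while Cars (-0.19) did not pass. Of 28 SR and hnRNP splicing factor genes 27 were lower (median -0.92, matched -0.77), among them Srsf2 (-1.21). All 8 chaperonin genes and 42 of 47 proteasome genes were lower, with medians of -0.99 and -0.81 at the 10.2nd and 9.53rd percentile of matched lists. Of 76 mitochondrial ribosomal protein genes 66 were lower (median -0.71, matched -0.59), and of 45 Nduf genes, mostly for respiratory complex I, 34 were lower (median -0.62, matched -0.67, so no further than others of their abundance). Genes named Zfp, for zinc finger proteins, were lower for 120 and higher for 5 of 286, with a median of -0.44 against -0.30, below all 10000 matched lists.

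Of 21 Nodal and BMP genes 10 were lower and 3 higher (median -0.26, matched -0.41). Lefty2 (-3.26) fell most and Nodal (0.57), Bmp7 (1.38) and Id2 (1.02), a target of BMP signalling, were the 3 higher. Of 6 Fgf genes Fgf15 (-2.90), Fgf17 (-2.38) and Fgf4 (-0.93) were lower and Fgf7 (0.87) higher. The noncoding RNA Rmrp, which acts in ribosomal RNA processing, rose from 193 and 213 to 484 and 440 FPKM (log2 fold change 1.18). As a small noncoding RNA it may be captured only in part by mRNA isolation, which limits these values. Trp53, the gene of p53, fell by 0.66 on the log2 scale, in contrast to its targets.

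Slower elongation could lower the RNA of long genes. Among 5 equal bins of coding loci by length, the longest (59.1 kb or more) had a median log2 fold change of -0.30 and the shortest (7.28 kb or less) of -0.45. Within bins of expression the longest loci lay 0.0186 above the shortest (permutation p = 0.23), where a fall of at least 0.1 had been set as the mark of slower elongation. A bootstrap 95% interval, added after that result together with a changed rule for judging it (the first rule left it undecided), ran from -0.0114 to 0.0608. It leaves out a fall of that size with length, but not a difference of 0. The bootstrap resampled genes, not libraries. RNA levels need not follow the speed of elongation, so these values cannot decide whether elongation was slower.

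The slightly larger fall of genes with a WDR43 peak may reflect their higher expression. Within expression bins the difference was 0.0188, against -0.06 over all genes.

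Of 27 replication-dependent histone loci with a shCtl Ser2P peak, 9 lost one, against 227 of 2108 among all tested genes, a difference that was not tested. A single peak can span several of these clustered loci.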
